A study of Mus musculus with 4 samples.

How the data were processed

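The study compared 4F2A mouse embryonic fibroblasts given DMSO with those given CX-5461 at the start of doxycycline-induced reprogramming, with 4 libraries in 2 groups of 2. Per the labels, total RNA was extracted with TRIzol on day 2, mRNA was captured with poly(T) beads, and libraries were sequenced as paired-end reads of 150 bases on an Illumina NovaSeq instrument. The labels speak of 2 parallel replicates per group and do not say that these were separate cultures, so p-values measure only the spread between these samples, which may be technical. No batch or date was given. Groups and replicate numbers were taken from the sample titles, and columns of the table were matched to samples by the day, treatment and replicate number in their names. 0 columns were left unused.

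The authors deposited TPM values, a measure in which reads per gene are divided by gene length and by the library total, and each column summed to 1000000. Reads were cleaned on the BMKCloud platform, per the labels, and build mm10 was named in the submitters' processing notes. The aligner, the counter, the annotation and the gene lengths are not given in the sources used here. Dividing by the total makes every value relative to all others in a library, so a rise of abundant genes lowers the rest. Gene coordinates and exon lengths came from GENCODE M21 (mm10), matched by symbol for 30059 symbols, 494 of them through another name in RefSeq.

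Low TPM values fell on whole multiples of a unit set by the exon length, so read numbers were recovered as TPM times the exon length times a constant per library. Of 71273 values above 0 and under 10000 reads, 69.5% lay within 0.01 of a whole number, against 2% by chance. Among tested genes, 6136 had whole reads in every library, 8249 did not, for a cause that was not tested, and 236 had no length. Genes that may share reads with copies, pseudogenes or overlapping and antisense genes are uncertain, and Gapdh, a gene with many pseudogenes, was listed at only 81.6 to 115 TPM. Replicates were compared over genes with at least 20 whole reads: chi-square per degree of freedom was 14.6 for the DMSO pair (6059 genes) and 7.95 for the CX-5461 pair (6024 genes), so neither pair was a library copied under another name, and the spread between libraries was well above counting noise.

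Genes with a mean of at least 1 TPM over the 4 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend and robust), with no covariate. P-values were adjusted by Benjamini-Hochberg over all genes tested, and a gene passed at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and 3.75 prior ones. An exact permutation test of single genes was not used because 2 against 2 libraries cannot give a two-sided p below 0.333. 44 gene lists fixed before the data were examined were described by counts, and the 40 with at least 5 tested members were tested with camera (preset correlation 0.01), with an estimated correlation per list, on ranks and with fry, adjusted over the lists. With an estimated correlation, camera's p rests on the 2 residual degrees of freedom, so hardly any list could pass, whatever its shift. 13 members, all mitochondrially encoded, were matched under the symbols of the table.

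Genes were named by a rule written before the data were examined: the 12 higher and 12 lower genes with the largest differences that passed, had a mean of at least 5 TPM in the higher group, lay apart in all libraries and were not predicted genes or pseudogenes, 18 benchmark genes, and up to 4 members per list with the smallest adjusted p, or 2 where none passed. A gene chosen by this rule is not reported here. Other settings, also chosen then, were pseudocounts of 0.1 and 5, no filter and a filter of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without mitochondrially encoded and the 20 highest genes, limma without trend and robust options, a replicate block, other thresholds and each library left out. With 1 library left out, its group's lone library was assumed to vary like the other group. limma's voom on the recovered reads was added after the data were seen. Read recovery used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures matplotlib 3.10.9.

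The procedure was tested on simulated data: counts drawn for 14512 genes of the CX-5461 and DMSO comparison with the libraries' depths and a dispersion of 0.00704, with 200 genes changed. All 200 came from genes with a mean of at least 5 TPM, so recovery of lower genes was not tested. Every gene was given the same dispersion, estimated from genes with many reads. Of genes changed by 1.5-fold 59.7% were recovered, by 2-fold 98.5% and by 4-fold 98.5%. Of 212 genes called, 41 were false, more than the threshold of 0.05 promises, and 26 of those had a mean below 5 TPM. The limit first set on the false share of that test was exceeded and was then widened, so this error rate stands as a known weakness of the procedure, above all at low TPM. With no gene changed, 11 were called. A list raised by 1.3-fold was found by camera with the preset correlation (adjusted p = 1.13e-48) and missed with an estimated correlation (adjusted p = 0.116). Of the other lists, 39 tested in all, 0 were called. Simulated genes were drawn independently of each other. This part therefore does not test false list calls where members vary together, and does not favor the preset correlation for the real lists.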

Results

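Polyadenylated RNA was sequenced from 4F2A mouse embryonic fibroblasts on day 2 of reprogramming. These cells carry a doxycycline-inducible cassette of the 4 reprogramming factors Oct4 (gene Pou5f1), Sox2, Klf4 and Myc, and came, per the labels, from male homozygous embryos. Doxycycline was present for 48 h at 2 µg/mL. DMSO, the vehicle, or CX-5461 was added for 1 h on day 0. CX-5461 inhibits RNA polymerase I, the enzyme that transcribes ribosomal RNA genes. Each of the 2 groups had 2 libraries, numbered 2 and 3. As deposited, TPM values of 21298 gene symbols lay above 0 in at least 1 library. Read numbers recovered from the TPM values came to 35.5M and 37.6M in the DMSO libraries and 35.6M and 35.3M in the CX-5461 libraries. Over 14621 genes, log2 values correlated at r = 0.984 between the DMSO libraries, at 0.986 between the CX-5461 libraries and at 0.949 to 0.954 across groups. These correlations run across genes, which are not independent replicates. DMSO replicate 3 stood apart in composition: the mitochondrially encoded share of TPM was 15.3% in DMSO replicate 3 and 9.96%, 9.20% and 9.24% in the other libraries. Values below are means ± SD of TPM over n = 2 libraries. Differences are CX-5461 minus DMSO on the log2(TPM + 1) scale, which understates the change of low genes.

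The comparison of CX-5461 with DMSO asked how brief CX-5461 treatment at the onset of reprogramming changed the transcriptome on day 2. Activity of RNA polymerase I was not measured, so the changes are those after CX-5461, by whatever route. Genes of mitosis fell furthest. Plk1, a kinase that drives mitotic progression (chromosome 7, 122159439 to 122169873, mm10), fell from 102 ± 0.38 to 1.58 ± 0.391 TPM (log2 difference -5.33, limma adjusted p = 0.000163). Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361), fell from 91.3 ± 9.47 to 1.67 ± 0.118 TPM (log2 difference -5.11, adjusted p = 0.000163). Ppp2r2c, a regulatory subunit of protein phosphatase 2A, rose from 1.40 ± 0.306 to 22.1 ± 0.953 TPM (adjusted p = 0.000395). Alox5, the 5-lipoxygenase that starts leukotriene synthesis, rose from 3.21 ± 0.487 to 34.8 ± 2.95 TPM (0.000359), and Wnt4, a secreted Wnt ligand, from 8.37 ± 1.38 to 66.4 ± 7.85 TPM (0.000443). In all, 1694 genes were higher and 1201 lower of 14621 tested with limma at an adjusted p under 0.05. Falls were the larger changes: 157 genes fell and 43 rose by 4-fold or more.

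The 12 lower genes with the largest differences were all genes of cell division or DNA synthesis: after Plk1 and Mki67 came Ccnb2 and Ccnb1, the B-type cyclins of mitosis (log2 differences -4.52 and -4.04). The others were Ckap2l (-4.41), Pimreg (-4.28), Pbk (-4.20), the DNA topoisomerase Top2a (-4.16), the PCNA-binding Pclaf (-4.08), the abscission protein Cep55 (-4.08), the spindle protein Nusap1 (-4.07) and the kinesin Kif2c (-4.06). Their adjusted p ran from 0.000163 to 0.000443, and each stayed past the threshold whichever library was left out. Among the 12 higher genes, the homeobox gene Nkx2-9 rose from 2.15 ± 0.332 to 25.3 ± 1.75 TPM and the mitochondrial creatine kinase Ckmt1 from 2.18 ± 0.0519 to 25.1 ± 0.294 TPM. Sytl1, a synaptotagmin-like protein of vesicle traffic, rose from 4.75 ± 2.25 to 40.3 ± 5.23 TPM and Svop, a synaptic vesicle protein, from 4.43 ± 1.76 to 37.2 ± 2.13 TPM. Scn3b, a sodium channel subunit, rose from 3.85 ± 0.154 to 30.7 ± 3.97 TPM and Sprr1b, a component of the cornified envelope of skin, from 0.781 ± 0.221 to 9.22 ± 1.33 TPM. The other 3 were microRNA loci with few reads inside longer genes. Mir5620 (chromosome 7, 7298891 to 7298946) lies inside Clcn4 on the opposite strand, was listed at 0 in both DMSO libraries and had 11.5 and 4 reads in the CX-5461 libraries. Mir7027 (chromosome 5, 114404468 to 114404539) lies inside Ube3b and had 7 and 8.5 reads there. Mir2139 (chromosome 4, 139967526 to 139967620), at 14.5 ± 0.916 TPM with CX-5461, lies inside Klhdc7a, which itself was higher by 2.09 (adjusted p = 0.00101), so reads of the locus and of its host could not be separated. Here and below, a lost call is given for the library whose omission gave the highest adjusted p. The same call may also have ended without other libraries, so such a sentence does not list every call lost without that library. With a CX-5461 library left out, the spread came from the DMSO pair alone. Leaving out CX-5461 replicate 3 ended the call of Mir2139 (adjusted p = 0.0626).

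Genes of the cell cycle fell almost throughout. Of the 77 measured genes of G2/M and mitosis, 73 fell and 2 rose (73 and 2 adjusted over the list alone), with a median log2 difference of -3.0 (camera adjusted p = 1.76e-54, and adjusted p = 0.25 with an estimated correlation). Of 59 genes of G1/S and DNA replication, 56 (57 adjusted over the list alone) fell and 0 rose, with a median of -1.66 (camera adjusted p = 1.25e-38, and adjusted p = 0.25 with an estimated correlation). Mcm5 and Mcm3, subunits of the replicative helicase, fell from 55.6 ± 7.57 to 3.30 ± 0.515 TPM and from 73.7 ± 9.23 to 8.32 ± 1.41 TPM. Uhrf1, which carries DNA methylation through replication, fell from 48.4 ± 7.02 to 2.79 ± 0.0681 TPM, and Clspn, an adaptor of the replication checkpoint, from 15.9 ± 0.198 to 0.554 ± 0.0413 TPM. The rises in the mitotic list were those of Psrc1 (0.62) and Gtse1 (0.54), both described as p53-responsive genes, while Bub3 (-0.12) and Tubb4b (-0.05) did not pass. Rfc4 (-0.54), Gins2 (-0.33) and Ubr7 (-0.13) were the members of the replication list that did not pass. With 1 library left out, Rfc4 ranged over -0.76 to -0.32, Gins2 over -0.48 to -0.17, Ubr7 over -0.21 to -0.06, Bub3 over -0.18 to -0.05 and Tubb4b over -0.09 to -0.01. Rfc4 passed under median-of-ratios scaling and rescaling without the highest genes. Members singled out because a count was 5 or fewer, here and below, were chosen after their values were seen. Of 59 genes of DNA repair and the damage response, 32 fell and 2 rose (35 and 2 adjusted over the list alone). Lig1, the ligase of lagging-strand synthesis, fell from 36.9 ± 0.131 to 7.15 ± 0.447 TPM, and Usp1, a deubiquitinase of the Fanconi pathway, from 90.5 ± 1.45 to 26.9 ± 1.06 TPM. The median was -0.76 (camera adjusted p = 3.50e-15, and adjusted p = 0.397 with an estimated correlation). Msh6 (0.90), a mismatch repair protein, and Rad51d (0.42) rose. 7 members of the repair list also stood in the cell cycle lists, and of the 52 others 25 fell (median -0.54). With CX-5461 replicate 2 left out, the call lost was that of Rad51d (adjusted p = 0.211). When CX-5461 replicate 3 was left out, calls ended for Psrc1 (adjusted p = 0.113), Gtse1 (0.142) and Msh6 (0.0591).

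**Figure D1:**
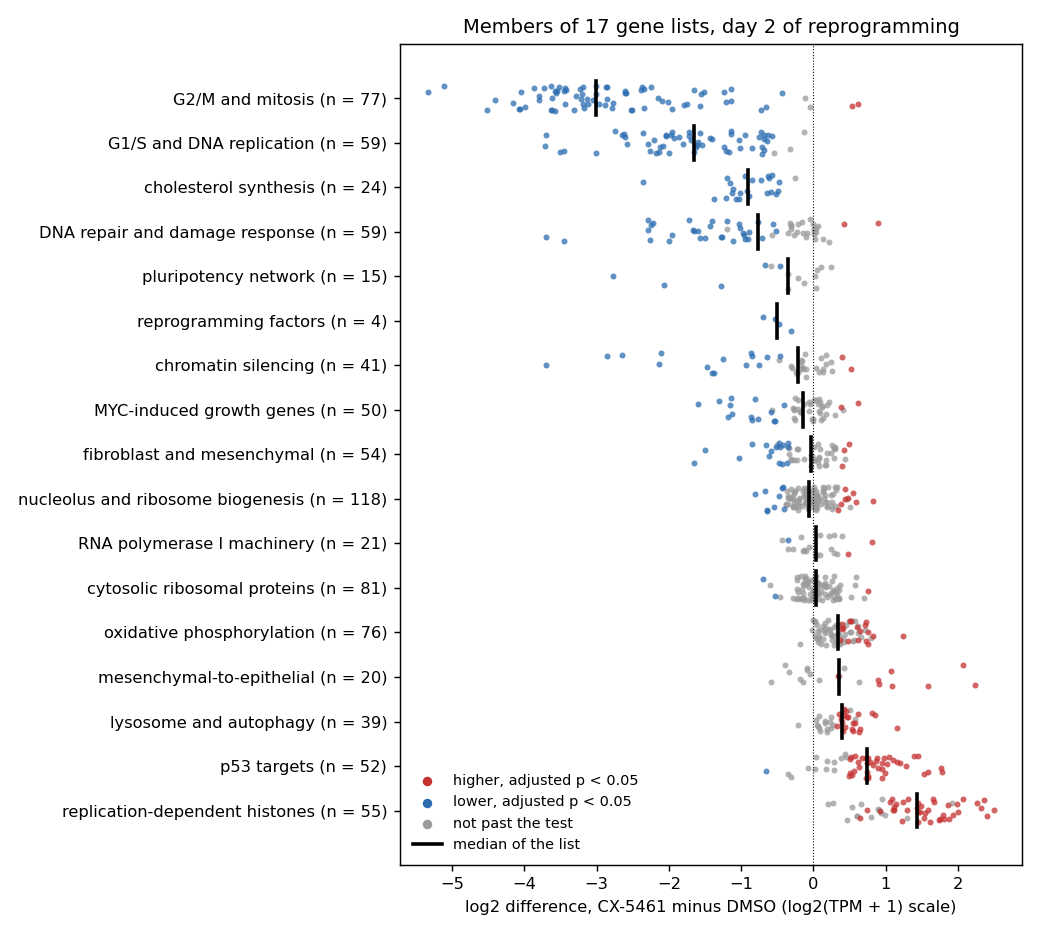
Each point is the log2 difference (x axis, CX-5461 minus DMSO on the log2(TPM + 1) scale) of a measured member of a fixed gene list (y axis), red where higher and blue where lower past the limma test and grey where not, with a black bar at the median. Medians ran from -3.0 for the mitosis list to 1.43 for the histone list, and the RNA polymerase I and ribosomal protein lists lay around 0.

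Targets of the transcription factor p53 rose. Of 52 measured, 39 rose and 1 fell (41 and 2 adjusted over the list alone), with a median log2 difference of 0.75 (camera adjusted p = 5.50e-15, and adjusted p = 0.397 with an estimated correlation). Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (chromosome 17, 29090976 to 29100727), rose from 700.1 ± 24.7 to 1701 ± 90.4 TPM (log2 difference 1.28, adjusted p = 0.000959). Mdm2, the ubiquitin ligase that degrades p53, rose from 215 ± 0.915 to 481 ± 36.7 TPM, the death receptor Fas from 32.6 ± 3.22 to 113 ± 0.320 TPM and the reductase Dcxr from 120.2 ± 17.3 to 412 ± 2.62 TPM. Ckap2, a spindle protein, was the member that fell (-0.65, adjusted p = 0.00851). Trp53, which encodes p53 itself, stood at 139 ± 10.2 and 125 ± 6.71 TPM and did not pass (adjusted p = 0.334). Of 31 apoptosis effectors, 8 rose and 2 fell (8 and 3 adjusted over the list alone). Rises included those of Fas, Pmaip1 (Noxa, 1.39), the death receptor Tnfrsf10b (0.72) and Bbc3 (Puma, 0.75), whereas Aifm1 (-0.60) and Casp12 (-0.53) fell. The apoptosis list as a whole did not shift (median 0.09, and 0.04 without CX-5461 replicate 2, camera adjusted p = 0.352). Of 17 regulators and markers of senescence, 5 rose and 9 fell (6 and 9 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 0.0510), and the list passed without CX-5461 replicate 3 (median -0.72, adjusted p = 0.0345), and with a filter of 5 TPM (median -0.67, adjusted p = 0.0350). This list mixes inhibitors and markers that need not move alike in senescence, so its median does not tell whether senescence rose or fell. Of its members, 1 also stood in a cell cycle list, and 8 of the 16 others fell (median -0.41). The rises were those of the cell cycle inhibitors Cdkn1a, Cdkn2a (0.77), Cdkn2b (0.70), Rb1 (1.11) and Rbl2 (0.51). Lmnb1, the lamin B1 gene, fell from 87.3 ± 8.32 to 11.2 ± 0.585 TPM, Hmgb2, a chromatin protein, from 41.9 ± 1.5 to 2.66 ± 0.663 TPM, and Cdkn2c, another kinase inhibitor, from 21.1 ± 1.09 to 5.80 ± 0.565 TPM. Bmi1 (0.25), Glb1 (0.16) and Trp53 (-0.14, and -0.22 to -0.07 with 1 library left out) did not pass. Immediate early and serum response genes shifted up, with a median of 0.26 (camera adjusted p = 0.0119, and adjusted p = 0.728 with an estimated correlation), and of 0.19, 0.16 and 0.19 under median-of-ratios scaling, quantile normalization and rescaling without the highest genes. Of 28 measured, 9 rose and 0 fell (12 and 1 adjusted over the list alone), with rises of the growth inhibitors Btg2 (0.97) and Btg1 (0.54) and of the factors Atf3 (1.01) and Junb (0.70). Cdkn1a, Mdm2, Fas, Dcxr, Pmaip1, Lmnb1, Hmgb2 and Cdkn2c passed whichever library was left out. The calls that ended without CX-5461 replicate 2 were those of Ckap2 (adjusted p = 0.0933) and Casp12 (0.201). No call remained without CX-5461 replicate 3 for Tnfrsf10b (adjusted p = 0.0739), Bbc3 (0.0719), Aifm1 (0.126), Cdkn2a (0.176), Cdkn2b (0.104), Rb1 (0.0549), Rbl2 (0.225), Btg1 (0.166), Btg2 (0.0705), Atf3 (0.0718) and Junb (0.130).

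Replication-dependent histone genes, whose messages normally peak in S phase and carry a stem-loop in place of a poly(A) tail, rose. Of 55 measured, 40 (50 adjusted over the list alone) rose and 0 fell, and the median log2 difference was 1.43 (camera adjusted p = 5.72e-20, and adjusted p = 0.25 with an estimated correlation). H4c8 rose from 18.4 ± 2.45 to 109 ± 9.71 TPM and H4c17 from 72.5 ± 6.0 to 377 ± 52.3 TPM. H2ac19 rose from 41.7 ± 0.938 to 123 ± 0.271 TPM and H3c2 from 23.0 ± 0.693 to 86.2 ± 6.99 TPM. Each of these passed whichever library was left out. Summed over the list, TPM came to 1145 and 1072 in the DMSO libraries and 3313 and 3456 in the CX-5461 libraries. Near-identical coding sequences within this family make single members uncertain, and a library made by poly(T) capture holds only part of these messages.

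**Figure D2:**
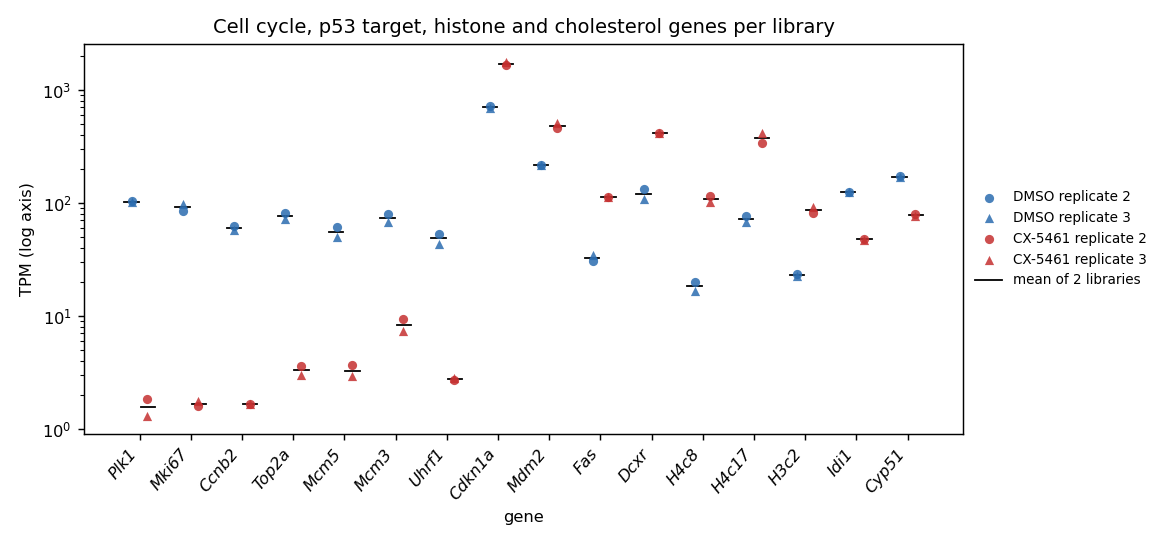
TPM on a log axis (y axis) of cell cycle, p53 target, histone and cholesterol genes (x axis) in each DMSO (blue) and CX-5461 (red) library, with circles for replicate 2, triangles for replicate 3 and a black bar at the mean of n = 2. Plk1 lay at 103 and 102 TPM with DMSO and at 1.86 and 1.31 TPM with CX-5461.

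All 4 reprogramming factors fell (4 adjusted over the list alone), by less than 2-fold. Pou5f1 fell from 145 ± 15.3 to 104 ± 5.13 TPM (log2 difference -0.48, adjusted p = 0.0293) and Sox2 from 224 ± 28.1 to 154 ± 10.2 TPM (-0.53, adjusted p = 0.0284). Klf4 fell from 340.2 ± 14.3 to 273 ± 4.80 TPM (-0.32, adjusted p = 0.0446) and Myc from 353 ± 32.4 to 217 ± 1.04 TPM (-0.70, adjusted p = 0.00643). The table does not separate cassette from endogenous transcripts. Of 15 measured genes of the pluripotency network, 5 (5 adjusted over the list alone) fell and 0 rose (camera adjusted p = 0.00781, and adjusted p = 0.661 with an estimated correlation). Mybl2 fell from 15.8 ± 0.910 to 1.45 ± 0.207 TPM and L1td1 from 8.71 ± 0.948 to 1.3 ± 0.104 TPM, and the others were Etv5 (-0.67), the threonine dehydrogenase gene Tdh (-1.28) and Trim28 (-0.46). Mybl2, a cell cycle transcription factor, stood in a cell cycle list too. The list's median was -0.35, and -0.07 without DMSO replicate 2 and -0.17 without CX-5461 replicate 2. Nanog, a core pluripotency gene, stood at 0.0868 ± 0.123 and 0.0221 ± 0.0313 TPM and the epithelial Epcam at 0.320 ± 0.174 and 0.0904 ± 0.128 TPM, below the filter. Leaving out 1 CX-5461 library or the other ended the calls of the 4 factors, Etv5, Tdh and Trim28. Those of Etv5 and Tdh ended whichever library was left out. With 1 library left out, Pou5f1 ranged over -0.59 to -0.37 and Sox2 over -0.66 to -0.40. Klf4 ranged over -0.36 to -0.27 and Myc over -0.79 to -0.61. Etv5 ranged over -0.85 to -0.48, Tdh over -1.36 to -1.20 and Trim28 over -0.57 to -0.35. Without the filter on low values, or without limma's trend and robust options, Pou5f1, Sox2, Klf4, Etv5 and Trim28 did not pass. Klf4 did not pass with a replicate block either.

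Some epithelial genes rose, and fibroblast genes fell more often than they rose. Of 20 measured genes of the mesenchymal-to-epithelial transition, an early step of reprogramming, 8 rose and 0 fell (8 and 1 adjusted over the list alone). Dsp (desmoplakin) rose from 24.1 ± 0.679 to 105 ± 13.9 TPM and the membrane protease gene St14 from 4.60 ± 0.310 to 25.4 ± 2.43 TPM. The desmosomal Perp, also a p53 target, rose from 231 ± 12.2 to 696 ± 110.1 TPM and the tight junction gene F11r from 42.0 ± 4.78 to 78.4 ± 4.39 TPM (adjusted p = 0.00535). Cdh1, which encodes E-cadherin, stood at 4.54 ± 0.911 and 2.70 ± 0.870 TPM and did not pass (-0.59, adjusted p = 0.143, and -0.83 to -0.35 with 1 library left out). Keratinocyte genes, given below, rose in part as well (5 of 11), as did Sprr1b (2.52) of the cornified envelope. Whether the epithelial transcripts came from cells in transition or from keratinocytes was not measured. The list did not pass as a whole (median 0.35, camera adjusted p = 0.0510), but did without CX-5461 replicate 2 (median 0.38, adjusted p = 0.0182), and its median was 0.14 without DMSO replicate 3. It passed under median-of-ratios scaling, quantile normalization and rescaling without the highest genes (medians 0.28, 0.30 and 0.26, adjusted p = 0.0242, 0.0185 and 0.0291), and with a filter of 5 TPM (median 0.89, adjusted p = 0.000641). By library, the mitochondrially encoded share of TPM was 15.3% in DMSO replicate 3 and 9.96%, 9.20% and 9.24% in the other libraries. Of 54 fibroblast and mesenchymal genes, 16 fell and 3 rose (18 and 6 adjusted over the list alone), and 35 did not pass. Col6a3, a collagen VI chain, fell from 387 ± 42.8 to 136 ± 5.93 TPM, the proteoglycan gene Lum from 156 ± 2.23 to 75.7 ± 0.118 TPM and the elastin gene Eln from 75.0 ± 17.4 to 22.9 ± 1.22 TPM. Pdgfra, a growth factor receptor, fell from 33.1 ± 0.599 to 18 ± 0.912 TPM (adjusted p = 0.00415) and the surface marker Thy1 from 451 ± 21.9 to 294 ± 34.4 TPM (adjusted p = 0.0145). Tgfb3 (0.50), the matrix protease Mmp2 (0.43) and the fibronectin gene Fn1 (0.40) rose. When CX-5461 replicate 2 was left out, the call ended for Tgfb3 (adjusted p = 0.139). The calls that ended without CX-5461 replicate 3 were those of F11r (adjusted p = 0.0771), Pdgfra (0.0620), Thy1 (0.154), Mmp2 (0.236) and Fn1 (0.266). Col1a1, a collagen I chain, stood at 3717 ± 853 and 3176 ± 36.2 TPM and did not pass (adjusted p = 0.416), but did without DMSO replicate 3 (-0.44), and stood at 0.03 without DMSO replicate 2. The fibroblast list shifted down, with a median of -0.03 and a mean of -0.16 (camera adjusted p = 0.0137, and adjusted p = 0.728 with an estimated correlation). Its call ended without CX-5461 replicate 3 (median -0.02, adjusted p = 0.0654), and its median was -0.12 without CX-5461 replicate 2, -0.05 without DMSO replicate 2 and -0.06 without DMSO replicate 3. Under median-of-ratios scaling, quantile normalization and rescaling without the highest genes it passed with larger falls (medians -0.10, -0.08 and -0.10, adjusted p = 0.00881, 0.00756 and 0.00574).

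Few genes of RNA polymerase I and the nucleolus passed, and those moved in both directions. In both lists the share that passed was below that of all tested genes (2895 of 14621). Of 21 measured genes of the polymerase I machinery, 2 rose and 1 fell (2 and 0 adjusted over the list alone). Polr1e, a polymerase subunit, rose from 22.8 ± 2.84 to 40.5 ± 1.19 TPM (adjusted p = 0.00812) and the initiation factor gene Rrn3 from 72.9 ± 2.65 to 103 ± 9.75 TPM (adjusted p = 0.0246). Ubtf, which binds the promoters of ribosomal RNA genes, fell from 69.8 ± 3.14 to 54.4 ± 3.11 TPM (adjusted p = 0.0473). Polr1a, the largest subunit, stood at 37.3 ± 0.517 and 34.7 ± 0.678 TPM and Polr1b at 24.1 ± 1.57 and 18.6 ± 1.66 TPM, and neither passed (adjusted p = 0.444 and 0.0828). The list had a median of 0.03 and a mean of 0.06 with a camera statistic below 0 (adjusted p = 0.957), and its median lay below 0 under each of the other scalings. It was 0.10 without DMSO replicate 2, 0.01 without DMSO replicate 3, 0.09 without CX-5461 replicate 2 and 0.02 without CX-5461 replicate 3. Of 118 nucleolar and ribosome biogenesis genes, 9 fell and 8 rose (9 and 7 adjusted over the list alone), with a median of -0.06 (camera adjusted p = 0.0510). The nucleolar list passed without DMSO replicate 3 (median -0.09, adjusted p = 0.0317), and its median was -0.01 without DMSO replicate 2 and -0.02 without CX-5461 replicate 2. It also passed, with larger falls, under median-of-ratios scaling, quantile normalization and rescaling without the highest genes (medians -0.13, -0.13 and -0.13, adjusted p = 0.0185, 0.00633 and 0.0160). With a filter of 5 TPM its adjusted p was 0.0333, and on ranks 0.0369. The chaperone gene Npm1 fell from 914 ± 40.1 to 679 ± 19.6 TPM (adjusted p = 0.0206) and Ncl, which encodes nucleolin, from 263 ± 12.6 to 198 ± 2.58 TPM (0.0230). Tcof1, which encodes treacle, fell from 76.1 ± 1.52 to 43.0 ± 0.270 TPM (0.00298), Nop56, of the box C/D particle, from 124 ± 2.53 to 77.4 ± 0.326 TPM (0.00464) and Dkc1, the pseudouridine synthase, from 49.2 ± 3.36 to 31.0 ± 1.11 TPM (0.00906). Rrp36, of ribosomal RNA processing, rose from 37.8 ± 3.14 to 67.6 ± 2.55 TPM (0.00474), and the methyltransferase gene Fbl stood at 71.0 ± 1.19 and 56.3 ± 6.38 TPM and did not pass (0.0794). Polr1b passed under each of the other scalings, and Fbl under quantile normalization and rescaling. With 1 library left out Fbl ranged over -0.45 to -0.22. No call remained without CX-5461 replicate 2 for Ubtf (adjusted p = 0.271) and Dkc1 (0.0948). Leaving out CX-5461 replicate 3 ended the calls of Polr1e (adjusted p = 0.0991), Rrn3 (0.209), Npm1 (0.232), Ncl (0.218), Tcof1 (0.0549), Nop56 (0.0837) and Rrp36 (0.0739). Ubtf and Rrn3 did not pass without the filter on low values, and Ubtf, Rrn3, Npm1 and Ncl did not without trend and robust options.

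**Figure D3:**
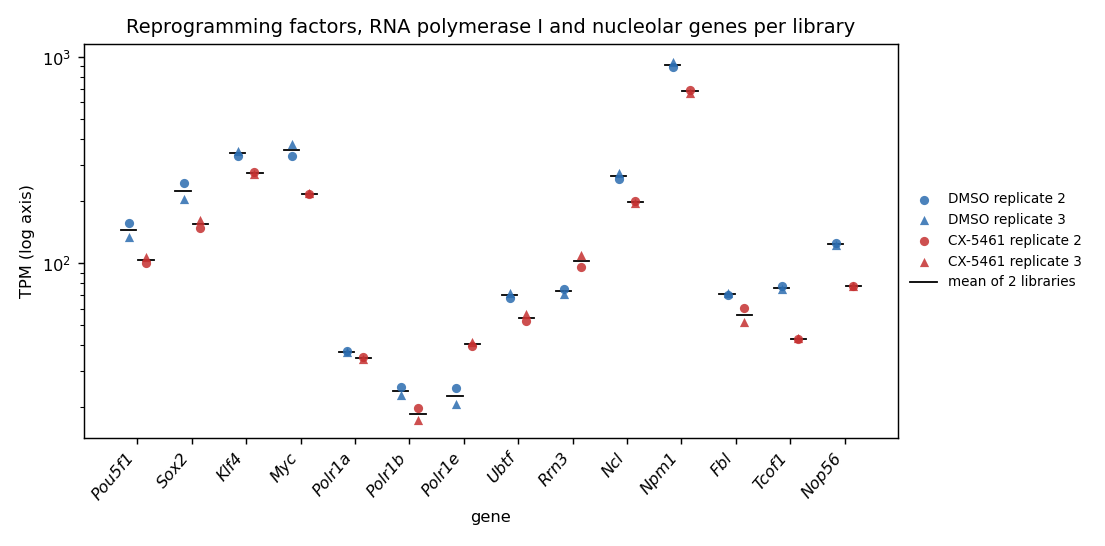
TPM on a log axis (y axis) of the reprogramming factors and of RNA polymerase I and nucleolar genes (x axis) in each DMSO (blue) and CX-5461 (red) library, with circles for replicate 2, triangles for replicate 3 and a black bar at the mean of n = 2. Both CX-5461 libraries lay below both DMSO libraries for Pou5f1, Sox2, Klf4 and Myc, and above them for Rrn3 and Polr1e.

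Ribosomal protein genes did not move as a group. Of 81 genes of cytosolic ribosomal proteins, 1 rose and 2 fell (0 and 0 adjusted over the list alone). Rps27l, a p53-responsive paralog of Rps27, rose from 402 ± 80.2 to 672 ± 14.9 TPM. Rpl10a fell from 591 ± 91.4 to 361 ± 16.3 TPM and Rpl3 from 922 ± 151 to 634 ± 1.48 TPM (adjusted p = 0.0206, 0.0153 and 0.0362). Their median was 0.04 and their mean 0.05 with a camera statistic below 0 (adjusted p = 0.583), and the median lay below 0 under each of the other scalings. Leaving out DMSO libraries turned the list: without DMSO replicate 2 it was higher (median 0.18, adjusted p = 0.0178) and without DMSO replicate 3 lower (median -0.11, adjusted p = 8.72e-05). Its median was -0.01 without CX-5461 replicate 2 and 0.09 without CX-5461 replicate 3. Members of this list varied together (estimated correlation 0.58), so camera's preset correlation of 0.01 understates the spread of the list. By library, the mitochondrially encoded share of TPM was 15.3% in DMSO replicate 3 and 9.96%, 9.20% and 9.24% in the other libraries. Of 77 mitochondrial ribosomal proteins, 5 (0 adjusted over the list alone) rose and 0 fell (median 0.13, camera adjusted p = 0.134), namely Mrpl24 (0.52), Mrps14 (0.91), Mrpl57 (0.78), Mrpl39 (0.36) and Mrpl1 (0.44). The median of that list was 0.08 without DMSO replicate 3, and 0.06, 0.07 and 0.06 under median-of-ratios scaling, quantile normalization and rescaling without the highest genes. Of 19 host genes of small nucleolar RNAs, 2 (2 adjusted over the list alone) fell, Snhg4 (-1.0) and Snhg5 (-0.63), and 0 rose (median -0.15, camera adjusted p = 0.121). The host gene list passed without DMSO replicate 3 (median -0.33, adjusted p = 0.0141), and its median turned to 0.03 without DMSO replicate 2 (adjusted p = 0.843). With CX-5461 replicate 2 left out, the calls lost were those of Mrpl24 (adjusted p = 0.157) and Snhg4 (0.108). When CX-5461 replicate 3 was left out, calls ended for Rps27l (adjusted p = 0.149), Rpl10a (0.158), Rpl3 (0.231), Mrps14 (0.164), Mrpl57 (0.201), Mrpl39 (0.281), Mrpl1 (0.232) and Snhg5 (0.166). The difference of Mrpl57 was 0.51 without DMSO replicate 3.

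Genes of cholesterol synthesis and uptake fell together. Of 24 measured, 23 (24 adjusted over the list alone) fell and 0 rose, with a median log2 difference of -0.91 (camera adjusted p = 2.14e-18, and adjusted p = 0.661 with an estimated correlation). Idi1, of the isoprenoid branch, fell from 125 ± 0.378 to 47.4 ± 0.290 TPM and the sterol demethylase gene Cyp51 from 170.1 ± 2.46 to 77.7 ± 1.75 TPM. The farnesyl diphosphate synthase gene Fdps fell from 70.9 ± 4.99 to 30.2 ± 1.6 TPM. These calls held whichever library was left out. Hsd17b7 did not pass (-0.26, adjusted p = 0.0932), but did under median-of-ratios scaling, quantile normalization and rescaling without the highest genes. Lysosome and autophagy genes rose: of 39, 21 (25 adjusted over the list alone) rose and 0 fell, with a median of 0.40 (camera adjusted p = 1.45e-07, and adjusted p = 0.661 with an estimated correlation). The protease genes Ctsd and Ctsb rose from 1845 ± 179 to 4089 ± 14.9 TPM and from 431 ± 35.3 to 759 ± 31.4 TPM. So did the galactosidase gene Gla from 36.8 ± 1.19 to 67.6 ± 7.08 TPM and the proton pump gene Atp6v0d1 from 268 ± 9.0 to 418 ± 19.9 TPM. Those calls ended without CX-5461 replicate 3 (adjusted p = 0.0554, 0.0829, 0.0666 and 0.112). The macrophage genes Lyz2 (0.65), Cd14 (0.96) and Adgre1 (0.90) rose as well, and 12 of 14 macrophage genes lay above 0 (see the cell type markers below). Whether the lysosomal transcripts came from fibroblasts or from macrophages was not measured.

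By camera with its preset correlation of 0.01, nuclear genes of oxidative phosphorylation shifted up and the genes encoded on the mitochondrial genome down. Estimated correlations between members were 0.57 and 0.98, so members moved together within libraries and these camera p-values are too small. By fry's directional test neither list passed (adjusted p = 0.201 and 0.407). Of 76 nuclear members, 17 (18 adjusted over the list alone) rose and 0 fell, with a median of 0.34 (camera adjusted p = 2.70e-06, and adjusted p = 0.728 with an estimated correlation). Cox8a, a subunit of cytochrome c oxidase, rose from 692 ± 3.16 to 981 ± 3.99 TPM, and the complex I genes Ndufa7, Ndufab1 and Ndufa13 by 0.76, 0.64 and 0.73 on the log2 scale. Of 13 mitochondrially encoded genes none passed over all genes or adjusted over the list alone. Their median was -0.40 (camera adjusted p = 0.00536, and adjusted p = 0.728 with an estimated correlation), with CYTB at 13625 ± 3964 and 8195 ± 244 TPM (adjusted p = 0.0692) and ATP8 at 9788 ± 3873 and 5576 ± 213 TPM (0.123). Both shifts were smaller without DMSO replicate 3. By library, the mitochondrially encoded share of TPM was 15.3% in DMSO replicate 3 and 9.96%, 9.20% and 9.24% in the other libraries. Without that library the oxidative phosphorylation median was 0.16 and the list still passed (adjusted p = 8.84e-05), and the mitochondrially encoded call ended (median -0.12, adjusted p = 0.0546). Without DMSO replicate 2 the median of the encoded genes was -0.71. CYTB and ATP8 passed with either DMSO library left out (-1.0 and -1.17 without DMSO replicate 2, -0.40 and -0.34 without DMSO replicate 3). Quantile normalization ended the mitochondrially encoded call (adjusted p = 0.614). Of 24 glycolysis genes, 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.0808). The glycolysis list passed without DMSO replicate 3 (median -0.11, adjusted p = 0.0141) and without CX-5461 replicate 2 (median -0.06, adjusted p = 0.0457). Without DMSO replicate 2 its median was -0.03 (adjusted p = 0.278). Under median-of-ratios scaling, quantile normalization and rescaling without the highest genes it passed (medians -0.14, -0.15 and -0.14, adjusted p = 0.0385, 0.0265 and 0.0365). The lactate transporter gene Slc16a1 (-0.83), Eno3 (-0.79) and Aldoc (-1.18) fell and Eno2 (0.82) rose. Of 25 hypoxia response genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone), with a median of 0.19 (camera adjusted p = 0.352). Plod2 (0.73), Adm (0.72), Car12 (0.98) and Bnip3l (0.46) rose and Aldoc fell. The calls that ended without CX-5461 replicate 2 were those of Ndufa13 (adjusted p = 0.15) and Adm (0.0989). No call remained without CX-5461 replicate 3 for Cox8a (adjusted p = 0.158), Ndufa7 (0.130), Ndufab1 (0.152), Slc16a1 (0.100), Eno3 (0.134), Aldoc (0.122), Eno2 (0.0979), Plod2 (0.0881), Car12 (0.128) and Bnip3l (0.182).

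Genes of growth, chromatin silencing and stress responses fell in part. Of 50 MYC-induced growth genes, 14 fell and 2 rose (15 and 3 adjusted over the list alone), with a median of -0.15 (camera adjusted p = 0.000174, and adjusted p = 0.728 with an estimated correlation). Pcna, the sliding clamp of DNA polymerases, fell from 152 ± 4.50 to 49.3 ± 3.94 TPM. Shmt2 and Psat1, of serine and one-carbon metabolism, fell from 162 ± 1.94 to 92.1 ± 1.29 TPM and from 207 ± 30.8 to 93.3 ± 0.915 TPM, and the RNA-binding Hnrnpa1 from 445 ± 19.5 to 243 ± 18 TPM. Odc1 (0.38) and Mycbp (0.61) rose. The median of this list was -0.08 without DMSO replicate 2, and -0.22, -0.25 and -0.22 under median-of-ratios scaling, quantile normalization and rescaling without the highest genes. Of 41 genes of chromatin silencing, 15 fell and 2 rose (16 and 2 adjusted over the list alone), with a median of -0.22 (camera adjusted p = 2.39e-06, and adjusted p = 0.728 with an estimated correlation). The maintenance DNA methyltransferase gene Dnmt1 fell from 73.8 ± 2.32 to 27.9 ± 0.282 TPM and the chromatin remodeler gene Hells from 24.1 ± 0.656 to 3.05 ± 0.811 TPM, and the Polycomb genes Eed (0.51) and Rnf2 (0.40) rose. 5 members were also cell cycle genes, and 10 of the 36 others fell. Of 40 genes of the integrated stress and unfolded protein responses, 13 fell and 5 rose (13 and 6 adjusted over the list alone), with a median of -0.09 (camera adjusted p = 0.0245, and adjusted p = 0.728 with an estimated correlation). The pseudokinase gene Trib3 fell from 28.1 ± 0.537 to 12.3 ± 0.824 TPM, the amino acid transporter gene Slc7a5 from 122 ± 18.5 to 48.0 ± 2.73 TPM and the asparagine synthetase gene Asns from 166 ± 10.1 to 85.0 ± 4.33 TPM. Sesn2 (0.75), Atf3 (1.01), Ddit3 (0.43), Cebpb (0.46) and Canx (0.33) rose. On ranks the stress list did not pass (adjusted p = 0.0637), and its median was -0.16, -0.17 and -0.17 under the same scalings, where it passed. Pcna, Dnmt1, Hells, Trib3 and Slc7a5 passed whichever library was left out. Leaving out CX-5461 replicate 2 ended the call of Mycbp (adjusted p = 0.221). With CX-5461 replicate 3 left out, the calls lost were those of Shmt2 (adjusted p = 0.0554), Psat1 (0.0548), Hnrnpa1 (0.0650), Odc1 (0.288), Eed (0.199), Rnf2 (0.217), Asns (0.0520), Sesn2 (0.0773), Atf3 (0.0718), Ddit3 (0.175), Cebpb (0.207) and Canx (0.346).

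Heat shock and antioxidant genes were mixed. Of 21 heat shock genes and chaperones, 4 rose and 2 fell (7 and 5 adjusted over the list alone). Hspb1 (0.62), Hspa1a (0.55), Hspa1b (0.53) and Dnajb1 (0.37) rose, and Stip1 (-0.49) and Fkbp4 (-0.31) fell. The near-identical Hspa1a and Hspa1b share most short reads. The list's median was -0.03 and its mean 0.03 (camera adjusted p = 0.672) and its median was -0.01, -0.09, 0.01 and -0.07 with DMSO replicate 2, DMSO replicate 3, CX-5461 replicate 2 and CX-5461 replicate 3 left out, and -0.10, -0.12 and -0.10 under median-of-ratios scaling, quantile normalization and rescaling without the highest genes. Of 26 NRF2 and oxidative stress genes, 3 rose and 3 fell (3 and 4 adjusted over the list alone). The heme oxygenase gene Hmox1 (0.74), the ferritin gene Fth1 (0.46) and G6pdx (0.31) rose. Gsr (-0.78), the cystine transporter gene Slc7a11 (-0.77) and Gsta4 (-0.33) fell. That list's median was 0.05 and its mean -0.02 (camera adjusted p = 0.708). The median was 0.09, 0.00, 0.04 and 0.01 with the same libraries left out in that order, and turned to -0.02, -0.05 and -0.03 under the same scalings. When CX-5461 replicate 2 was left out, calls ended for Hspa1a (adjusted p = 0.132) and Hspa1b (0.162). The calls that ended without CX-5461 replicate 3 were those of Hspb1 (adjusted p = 0.123), Dnajb1 (0.314), Stip1 (0.182), Fkbp4 (0.305), Hmox1 (0.0973), Fth1 (0.233), G6pdx (0.282), Gsr (0.0896), Slc7a11 (0.173) and Gsta4 (0.285).

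Inflammatory genes rose in part. Of 59 interferon response genes, 10 (9 adjusted over the list alone) rose and 0 fell (median 0.21, camera adjusted p = 0.0572). The interferon list passed without DMSO replicate 3 (median 0.26, adjusted p = 0.00152) and without CX-5461 replicate 2 (median 0.28, adjusted p = 0.0274). Median-of-ratios scaling, quantile normalization and rescaling without the highest genes each made it pass as well (medians 0.15, 0.23 and 0.16, adjusted p = 0.0385, 0.0239 and 0.0381), as did a filter of 5 TPM (median 0.31, adjusted p = 0.00717). Among the higher genes were the peptide transporter gene Tap1 (from 21.5 ± 1.55 to 64.5 ± 9.47 TPM), Parp10 (1.20), the class I histocompatibility gene H2-D1 (0.76) and Ifi35 (0.79). Of 41 NF-kB targets and secreted inflammatory factors, 9 rose and 6 fell (11 and 7 adjusted over the list alone), with a median of 0.17 (camera adjusted p = 0.352). The adhesion molecule gene Icam1 rose from 30.2 ± 2.65 to 127 ± 16.5 TPM, the urokinase gene Plau from 45.1 ± 0.819 to 105 ± 2.28 TPM and the cytokine gene Csf1 from 93.3 ± 1.90 to 198 ± 7.11 TPM. Igfbp5, an IGF-binding protein, fell from 95.3 ± 5.23 to 49.8 ± 1.08 TPM. Of 20 imprinted genes, 6 fell and 2 rose (7 and 4 adjusted over the list alone), with a median of -0.11 (camera adjusted p = 0.0983). Falls included those of the non-coding H19 (from 3705 ± 205 to 1792 ± 226 TPM), the transporter gene Slc38a4 (from 77.8 ± 10.4 to 32.8 ± 3.03 TPM), Mest (-0.98) and Cdkn1c (-0.74). The rises were those of Ndn (0.48, adjusted p = 0.0229) and Dlk1 (0.54, adjusted p = 0.0142). The imprinted list passed by fry (adjusted p = 0.0434, down), and its median was -0.16 without DMSO replicate 2 and -0.23 without DMSO replicate 3. Of 8 nuclear-retained transcripts, 2 (2 adjusted over the list alone) rose, Pisd-ps1 (0.79) and Neat1 (0.81), and 0 fell (median 0.22, camera adjusted p = 0.541). That list passed by fry (adjusted p = 0.0243, up), and its median was 0.12 without DMSO replicate 2. Tap1, Icam1, Plau, Csf1 and Slc38a4 passed whichever library was left out. No call remained without CX-5461 replicate 2 for Mest (adjusted p = 0.0527) and Cdkn1c (0.0713). Leaving out CX-5461 replicate 3 ended the calls of Parp10 (adjusted p = 0.0562), H2-D1 (0.0996), Ifi35 (0.0918), Igfbp5 (0.0503), H19 (0.0787), Pisd-ps1 (0.0973) and Neat1 (0.122).

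Markers of other cell types that an embryonic fibroblast culture can hold moved in both directions. By camera none of the 7 lists passed in the TPM values as deposited with all libraries, and by fry's directional test the endothelial and adipocyte lists did, both upward (adjusted p = 0.00589 and 0.0357). Of 14 macrophage genes, 3 (3 adjusted over the list alone) rose, the lysozyme gene Lyz2 (from 518 ± 14.5 to 815 ± 56.7 TPM), Cd14 (0.96) and Adgre1 (0.90), and 0 fell (median 0.28, camera adjusted p = 0.0510). Of 11 keratinocyte genes, 5 rose and 0 fell (5 and 2 adjusted over the list alone), with a median of 0.52 (camera adjusted p = 0.109). The integrin gene Itgb4 rose from 67.6 ± 1.53 to 154 ± 23.5 TPM, and Sfn (0.46), Dsc3 (1.19), Krt17 (1.23) and Krt16 (1.08) rose. Of 7 adipocyte genes, 3 (3 adjusted over the list alone) rose, Cd36 (1.19), Cebpa (0.95) and Plin4 (0.76), and 0 fell (median 0.53, camera adjusted p = 0.0808). Fabp4 (0.53), Dgat2 (0.29), Pparg (0.06) and Lpl (-0.02) did not pass, and with 1 library left out ranged over 0.33 to 0.72, 0.08 to 0.51, -0.24 to 0.36 and -0.06 to 0.02. Of 7 endothelial genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone). The VEGF receptor gene Kdr rose from 6.29 ± 0.180 to 24.0 ± 0.197 TPM, Eng rose (0.53) and Tek fell (-0.39), with a median of -0.18 and a mean of 0.16 (camera adjusted p = 0.953). Of 7 muscle genes, 3 rose and 1 fell (3 and 2 adjusted over the list alone), with a median of -0.07 (camera adjusted p = 0.854). Des (0.57), Mylpf (1.13) and Tnnc1 (0.96) rose, and the skeletal actin gene Acta1 fell from 53.9 ± 4.71 to 19.4 ± 4.91 TPM. Of 11 neural genes, 1 (1 adjusted over the list alone) fell, Ncam1 (-0.50), and 0 rose (median -0.07, camera adjusted p = 0.352). Of 8 cartilage and bone genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone). The osteocalcin gene Bglap rose (1.22) and the collagen gene Col11a1 fell (-0.66), with a median of -0.01 and a mean of 0.14 (camera adjusted p = 0.797). Without CX-5461 replicate 2 the macrophage list passed (median 0.42, adjusted p = 0.00530), as did the keratinocyte list (median 0.72, adjusted p = 0.0491), and the adipocyte list passed without CX-5461 replicate 3 (median 0.72, adjusted p = 0.0375). The macrophage list passed under median-of-ratios scaling, quantile normalization and rescaling without the highest genes (medians 0.22, 0.23 and 0.19, adjusted p = 0.0373, 0.0289 and 0.0372), and the adipocyte list under quantile normalization (median 0.55, adjusted p = 0.0424). The endothelial median turned to 0.10 without DMSO replicate 2 and 0.09 without CX-5461 replicate 3, and was -0.05 without DMSO replicate 3 and -0.29 without CX-5461 replicate 2. With DMSO replicate 2, DMSO replicate 3, CX-5461 replicate 2 and CX-5461 replicate 3 left out in turn, the muscle median was 0.13, -0.45, 0.06 and 0.13, the neural one -0.01, -0.07, 0.04 and -0.20, and the cartilage and bone one 0.07, -0.02, 0.02 and 0.05. Itgb4, Kdr and Acta1 passed whichever library was left out. With DMSO replicate 3 left out, the call lost was that of Krt16 (adjusted p = 0.127). When CX-5461 replicate 2 was left out, calls ended for Adgre1 (adjusted p = 0.107), Sfn (0.169), Krt17 (0.176) and Mylpf (0.157). The calls that ended without CX-5461 replicate 3 were those of Lyz2 (adjusted p = 0.121), Cd14 (0.110), Dsc3 (0.207), Cd36 (0.0549), Cebpa (0.131), Plin4 (0.161), Eng (0.161), Tek (0.222), Des (0.162), Tnnc1 (0.186), Ncam1 (0.144), Bglap (0.187) and Col11a1 (0.0964).

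Of 10 placental and extraembryonic genes, 1 rose and 3 fell (1 and 3 adjusted over the list alone). The trophoblast factor gene Gata3 rose (0.78) and Pdgfra (-0.85), Lama1 (-1.29) and Dab2 (-0.50) fell, with a median of 0.06 and a mean of -0.04 (camera adjusted p = 0.488). The median turned to -0.07 without DMSO replicate 2 and -0.08 without CX-5461 replicate 3, and was 0.23 without CX-5461 replicate 2. The calls of Gata3, Pdgfra, Lama1 and Dab2 ended without CX-5461 replicate 3 (adjusted p = 0.142, 0.0620, 0.0771 and 0.179). Genes of the 2-cell-like state, which nucleolar stress is known to induce in embryonic stem cells, were mostly below the filter. Of the 3 measured none passed (0 adjusted over the list alone), with Zfp809 at 29.6 ± 7.14 and 42.5 ± 5.68 TPM (adjusted p = 0.111) and Naalad2 at 3.02 ± 0.539 and 2.33 ± 0.278 TPM (0.401). The 1 measured erythroid gene, the embryonic globin gene Hbb-y (-0.31, adjusted p = 0.310), and the 2 germ line genes Xlr3b (0.19, adjusted p = 0.497) and Sycp3 (0.16, adjusted p = 0.789) did not pass either, nor adjusted over the list alone. Hbb-y passed without DMSO replicate 3 (-0.59) and stood at -0.03 without DMSO replicate 2. Sycp3 turned to -0.16 without DMSO replicate 3 and stood at 0.55 without CX-5461 replicate 2. With 1 library left out, Zfp809 ranged over 0.28 to 0.76, Naalad2 over -0.41 to -0.13 and Xlr3b over 0.06 to 0.33. Of 5 sex-linked genes, 0 passed over all genes and 0 adjusted over the list alone (median 0.12, and 0.08 without CX-5461 replicate 3, camera adjusted p = 0.708). Xist, the transcript of an inactive X chromosome, stood at 70.7 ± 1.12 and 64.5 ± 3.92 TPM beside the Y-linked Ddx3y at 32.6 ± 0.0515 and 42.0 ± 2.95 TPM, Eif2s3y at 21.8 ± 1.13 and 27.0 ± 1.46 TPM, Uty at 5.25 ± 0.242 and 5.81 ± 0.28 TPM and Kdm5d at 3.85 ± 0.239 and 3.45 ± 0.484 TPM. Transcripts of both kinds were thus listed in every library although the labels give male embryos.

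Across the 40 lists tested with limma's camera, 15 shifted with its preset correlation, 5 up and 10 down. With a correlation estimated per list, 0 of the 40 passed (lowest adjusted p = 0.25, 5 at an unadjusted p under 0.05). That form rests on 2 residual degrees of freedom and could hardly pass any list, so it does not decide for or against a shift. The estimated correlations themselves reached 0.98 for the mitochondrially encoded, 0.67 for the cholesterol and 0.57 for the oxidative phosphorylation list, against the preset 0.01. By fry's directional test 11 passed. Among the shifted lists these were p53 targets, DNA repair, G1/S, G2/M, replication-dependent histones, cholesterol synthesis and lysosome. The others, which camera did not call, were nuclear-retained transcripts (adjusted p = 0.0243, up), endothelium (0.00589, up), adipocyte (0.0357, up) and imprinted genes (0.0434, down). Shifted lists that did not pass by fry were pluripotency (adjusted p = 0.0588), fibroblast (0.0773), MYC (0.113), oxidative phosphorylation (0.201), stress response (0.126), immediate early (0.113), chromatin silencing (0.0546) and mitochondrially encoded (0.407). Leaving out 1 library moved the count of higher genes to 2067 without DMSO replicate 2, 949 without DMSO replicate 3, 299 without CX-5461 replicate 2 and 218 without CX-5461 replicate 3, and that of lower genes to 891, 846, 398 and 337.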

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

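Of the alternatives below, voom on recovered reads was chosen after the data were seen, and the others before. The main counts were 1694 genes higher, 1201 lower and 15 lists shifted. The count of higher genes was 1051 without the filter on low values, 1128 without trend and robust options, 406 with a log2 difference of at least 1 as well, and 2623 at an adjusted p under 0.1. That of lower genes was 2211 with voom (higher 2329) and 452 with the log2 limit. Without trend and robust options, calls ended for Pou5f1, Sox2, Klf4, Ubtf, Rrn3, Ncl, Npm1, Etv5, Rps27l, Rpl3, Mrpl24, Mrps14, Mrpl57, Mrpl39, Ndufa13, Stip1, Hspa1b, Fth1, Bnip3l, Btg1, Eng, Tek, Des, Bglap, Sfn, Dab2, Trim28, Mmp2, Fn1, Mrpl1, Rad51d, Cdkn2a, Rbl2, Odc1, Mycbp, Ddit3, Cebpb, Canx, Dnajb1, Fkbp4, G6pdx, Gsta4, Eed, Rnf2, Casp12, Krt16 and Ndn. Without the filter on low values they ended for Pou5f1, Sox2, Klf4, Ubtf, Rrn3, Etv5, Rps27l, Rpl3, Mrps14, Mrpl57, Mrpl39, Ndufa13, Slc7a11, Snhg4, Snhg5, Tek, Des, Tnnc1, Bglap, Cebpa, Krt17, Dab2, Trim28, Mmp2, Mrpl1, Rad51d, Cdkn2a, Rbl2, Odc1, Mycbp, Canx, Dnajb1, Fkbp4, G6pdx, Gsta4, Eed, Rnf2, Casp12, Krt16 and Ndn. With voom they ended for Tnnc1 and Bglap, and with a pseudocount of 5 for Bglap. With voom 14 named genes gained a call, among them Cdh1, Polr1b, Fbl, Zfp809, Ddx3y, Gins2, Hsd17b7, Jag1, H3f3a, H3f3b and Krt14. Without trend and robust options 1 named gene gained a call. Ddx3y and Krt14, stated as not past the test, passed with a filter of 5 TPM. Lists gained were the mesenchymal-to-epithelial, nucleolar, interferon and glycolysis ones with voom, the mesenchymal-to-epithelial, nucleolar, interferon and senescence ones with that filter and the nucleolar one on ranks. The list count was 0 with an estimated correlation, where 2 residual degrees of freedom could hardly let any list pass. Those limits on p and size act by construction, and the cause of the other shifts was not tested. With 1 library left out, higher genes ranged over 218 to 2067, lower genes over 337 to 891 and lists over 16 to 20, and fewer libraries were left to estimate the spread. In each setting, 0 called genes changed sign. With 1 library left out, or with another pseudocount, filter, variance option or the replicate block, this was fixed in advance and is no support. Only the other scalings and voom could have changed a sign. Both CX-5461 libraries of each called gene lay on the same side of both DMSO libraries. Of 210 named genes past the test, 84 passed in every set with 1 library left out and all kept their sign there. The cytosolic ribosomal protein list turned without DMSO replicate 2 (median 0.18, adjusted p = 0.0178) and was lower without DMSO replicate 3 (-0.11), and the cause was not tested. The other scalings called 49.1%, 49.9% and 49.1% of changed genes higher, against 58.5%, and shifted 20, 20 and 19 lists, as the median of all genes moved from 0.07 to 0.00, 0.02 and 0.00. Under each of these scalings the calls of Mrpl1, Mycbp, Canx, Dnajb1, G6pdx and Rnf2 ended, as did that of Fn1 under the median-of-ratios, those of Fth1 and Odc1 under the quantile and that of Mrpl39 under the rescaling without the highest genes. Calls gained were those of Polr1b, Rfc4, Hsd17b7 and Krt14 under the median-of-ratios, Polr1b, Fbl, Hsd17b7 and Krt14 under the quantile and Polr1b, Fbl, Rfc4, Hsd17b7 and Krt14 under the rescaling. The medians under these scalings, in that order, were 0.10, 0.10 and 0.10 for the NF-kB list, 0.12, 0.09 and 0.11 for the hypoxia list, 0.02, 0.03 and 0.02 for the apoptosis list, 0.06, 0.14 and 0.06 for the sex-linked list, -0.24, -0.15 and -0.08 for the endothelial list, -0.09, 0.01 and -0.09 for the muscle list, -0.13, -0.07 and -0.13 for the neural list, -0.07, -0.03 and -0.07 for the cartilage and bone list, 0.01, 0.07 and 0.01 for the placental list and -0.17, -0.13 and -0.17 for the imprinted list. With the replicate block, 1589 genes were higher, 1100 lower and 18 lists shifted, and 2498 calls were kept, but deviations of libraries with the same number correlated at only 0.0307 over 2 pairs, so no pairing of the libraries was found. The block ended the calls of Klf4, one of the cassette factors, and of Ubtf, Mrpl39, Mrpl1, Tek, Rad51d, Odc1, Canx, Dnajb1, Fkbp4, G6pdx and Gsta4. It gained those of Zfp809, CYTB, Rfc4 and Krt14, and the mesenchymal-to-epithelial, senescence and macrophage lists.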

Other observations

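The genes of this and the next paragraph were chosen after their values were seen, and of the tests further down all but those on summed histone TPM and on small RNA genes were chosen after the results were seen. Genes outside the fixed lists with large rises included receptors and secreted proteins. Notch3, a Notch receptor, rose from 22.9 ± 3.0 to 98.1 ± 8.96 TPM (limma adjusted p = 0.000690) and the ligand gene Jag2 from 2.03 ± 0.512 to 11.8 ± 3.41 TPM (0.00449), whereas Jag1 (0.34, but past the test without DMSO replicate 2, at 0.47, and 0.20 without DMSO replicate 3) and the Notch targets Hes1 (-0.08, and -0.14 to -0.03 with 1 library left out) and Hey1 (0.45, and 0.28 to 0.63) did not pass. Ltb4r1 and Ltb4r2, receptors of leukotriene B4, rose from 6.31 ± 1.64 to 30.1 ± 2.08 TPM and from 4.10 ± 0.881 to 26 ± 5.14 TPM (adjusted p = 0.00176 and 0.00161), as did Alox5, while Alox5ap, the activator of that lipoxygenase, did not pass, at 5.33 ± 0.514 and 5.75 ± 0.0730 TPM. The secreted peroxidase gene Gpx3 rose from 91.7 ± 5.12 to 491 ± 54.1 TPM, the protease inhibitor gene Serpina3n from 88.2 ± 4.95 to 404 ± 14.2 TPM, the matrix gene Ltbp2 from 88.3 ± 5.91 to 298 ± 3.51 TPM and the arginine synthesis gene Ass1 from 212 ± 19.97 to 624 ± 40.4 TPM. Grhl3, a transcription factor of skin barrier formation, rose from 5.52 ± 0.655 to 29.3 ± 5.78 TPM and Sbsn, of the same tissue, from 31.5 ± 2.80 to 130.2 ± 12.7 TPM. All these calls held with each library left out in turn.

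Among lower genes, Crabp1, a binding protein of retinoic acid, fell from 477 ± 1.93 to 169 ± 4.95 TPM, the mitochondrial isocitrate dehydrogenase gene Idh2 from 129 ± 19.5 to 49.5 ± 6.52 TPM, the fatty acid elongase gene Elovl6 from 70.1 ± 0.423 to 24.8 ± 3.52 TPM, the branched-chain aminotransferase gene Bcat1 from 55.7 ± 4.05 to 18.3 ± 2.94 TPM and the chromatin gene Dek from 107 ± 7.75 to 40.3 ± 1.75 TPM. Foxm1 and E2f1, transcription factors of mitotic and S phase genes, fell from 39.6 ± 2.52 to 4.05 ± 0.207 TPM and from 42.2 ± 2.89 to 26.8 ± 1.82 TPM. Genes of histone variants outside the replication-dependent list moved apart: H2az1 fell from 294 ± 77.7 to 126 ± 3.03 TPM, H2ax from 168 ± 27.4 to 82.4 ± 3.53 TPM and H1f10 from 29.9 ± 4.52 to 8.22 ± 0.590 TPM, H2aj rose from 79.2 ± 17 to 152 ± 14 TPM, and H3f3a (0.34), H3f3b (0.27) and H1f0 (0.12, and 0.08 to 0.16 with 1 library left out) did not pass. Without DMSO replicate 2, H3f3a and H3f3b passed (0.56 and 0.38), and without DMSO replicate 3 they stood at 0.13 and 0.16. Slbp, which binds the stem-loop of histone messages, fell from 23.0 ± 0.969 to 10.9 ± 0.0907 TPM (adjusted p = 0.00322). The calls of E2f1, H2az1, H2ax and H2aj ended with 1 library left out (adjusted p = 0.128 without CX-5461 replicate 3, 0.0973 without CX-5461 replicate 3, 0.0708 without CX-5461 replicate 2 and 0.132 without CX-5461 replicate 3).

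Replication-dependent histone genes were higher while genes of S phase were lower. Other protein-coding genes with exon lengths from the 10th to the 90th percentile of the histone genes had a median log2 difference of 0.17 (1136 genes), far below 1.43, which argues against a rise of short genes in general. The log2 ratio of summed histone TPM was 1.61, which argues against reads merely moving between near-identical copies. Small nucleolar, Cajal body and nuclear RNA genes, which also lack a poly(A) tail, had a median of -0.071 (interquartile range -0.62 to 0.68), but held a median of only 4.88 reads per library, and 18 of 239 reached 20. The bound set for them earlier was met but decides nothing at such read numbers, so more RNA without a tail in the CX-5461 libraries, and more histone message with a tail as described for cells leaving the cycle, cannot be told apart.

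The cassette factors were lower after CX-5461. Under the other scalings each difference stayed at -0.39 or below (highest limma adjusted p = 0.0313), so the falls did not depend on the choice among these scalings. All of them are relative, and total RNA per cell was not measured. A lower level of the shared transcript alone might give equal falls, and the differences spanned 0.38, or 3.13 SE between Myc and Klf4, while Pou5f1 and Sox2 lay 0.05 apart. A rule of 2 SE set earlier would have ruled equal falls out. A studentized range test on limma's errors replaced it, because the extremes were picked from the data, and needs 3.51 SE. Both the SE and this test treat the 4 genes as independent, though all were measured in the same 4 libraries, so the SE may be wrong. Equal and unequal falls were thus not told apart with 2 libraries per group.

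Of 65 tested markers of other cell types, 17 were higher and 4 lower after CX-5461, against 1694 and 1201 of 14621 over all tested genes. A smaller share of fibroblasts alone would raise markers that fibroblasts lack, and 4 markers fell (Tek, Acta1, Ncam1 and Col11a1). Whether the fibroblasts themselves expressed these 4 was not measured, so their falls do not decide on that share. All tested macrophage genes together had a median of 0.28 (12 of 14 above 0) and all keratinocyte genes one of 0.52 (9 of 11). Among the latter Krt14 (-0.87), Krt5 (0.57) and Krt10 (0.52) did not pass and lay on both sides of 0, and Krt14 stood at -0.51 without CX-5461 replicate 2, passed without CX-5461 replicate 3 (-1.22) and under the other scalings, and Krt10 stood at 0.94 and 0.11 without these libraries. More macrophages or keratinocytes after CX-5461, which would add to the lysosomal and epithelial rises, and a change of expression within the cultured cells cannot be told apart, since neither list passed in the values as deposited, the macrophage list did under the other scalings, and cell composition was not measured here.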
